A study of Mus musculus with 15 samples.

How the data were processed

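RNA was profiled in E14 cells, a mouse embryonic stem cell line grown on gelatin with serum and leukemia inhibitory factor, per the labels' protocols. Cells received a non-targeting siRNA (siNT) or an siRNA against Rpl11, Rpl14, Rpl18 or Rpl23, each of which encodes a protein of the large (60S) ribosomal subunit. The sample titles give 48 h, whereas the treatment protocol in the labels gives harvest after 3 days of knockdown; which of them applies was not settled here. Each of the 5 groups had 3 libraries, prepared with a stranded kit for polyadenylated RNA, per the labels' protocols.

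The deposited values are FPKM per gene, made by the authors with STAR and Cuffnorm on genome build mm9, per the submitters' processing notes. Versions and the gene annotation are not given in the sources used here. The libraries came in separately normalized tables of 24819 genes each. The first held replicates 1 and 2 of all 5 groups (10 libraries) and the second held the third library of each group (5 libraries). The first table also held 2 columns that match no sample of this series, and these were not used. The gene annotation and transcripts used for length and GC content belong to another build than mm9, so no coordinates are given. Cuffnorm's settings are not given in the sources used here; if libraries were rescaled to each other, a shift shared by most transcripts of a group cannot be recovered.

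FPKM carries no total count, and the absolute depth is unknown. The step that 1 read makes in low values (0.005 to 0.15 FPKM) gave the depth of each library relative to the first library of its table. Relative depths were 0.698 to 1.39 in the first table and 1.00 to 1.26 in the second. Replicates 1 and 2 of a group correlated across genes with r of 0.996 to 0.998, and the variance of their differences was 1.21 to 1.56 times that of counting noise. That ratio rests on read counts inferred from transcript length for 388 to 469 genes with 1 transcript, so it is approximate. No pair was treated as a duplicate. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

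Tests used log2(FPKM + 1), which understates changes of genes with low FPKM, with no further scaling. Genes at 1 FPKM or more in at least 2 of the 10 libraries of the first table were kept (12249 genes). A linear model with 1 term per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend), which left 5 residual degrees of freedom and shared 1 estimate of the spread per gene over all groups. Contrasts were each knockdown against siNT, siRpl11 against the mean of the other 3 knockdowns, the differences between pairs of knockdowns, and a moderated F test over the 4 knockdowns. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The third libraries entered no test of this main fit. They gave the sign and size of each difference within their own table, and a covariance with the first table. They were tested only in the alternative fit of all 15 libraries.

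Before the data were examined, 21 gene lists were fixed: untargeted 60S and 40S ribosomal proteins, p53 targets, genes of the 2-cell-like state and its regulators, pluripotency, formative and primed pluripotency, trophectoderm, primitive endoderm, mesoderm, neuroectoderm, ribosome biogenesis, ATF4 targets of the amino acid and stress response, unfolded protein response, G1-S and DNA replication, G2-M, interferon response, germline, fibroblast and feeder markers, translation factors and 5-prime TOP genes, and mitochondrially encoded genes. None of the mitochondrially encoded genes was found under these symbols in the tables, which left 20 lists. Of 48 genes fixed for the 2-cell-like list, 42 were in the table and 32 passed the filter. Members low in siNT could pass it through the groups where they were high, so the direction of the tested members may be partly set by the filter. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 100 tests (20 lists in 5 contrasts). Of these, 52 were called. With an estimated correlation 0 were called, and the smallest adjusted p was 0.194. That setting also makes camera rest on the 5 residual degrees of freedom, so it can lose calls for a reason other than correlation. Pluripotency genes in siRpl14 had an estimated correlation of -0.025, under the preset one, yet camera's unadjusted p went from 0.00562 to 0.0262. A call lost for that list thus does not show that correlation between its genes had made it. Estimated correlations ranged from -0.074 (interferon response genes) to 0.83 (40S proteins). They were 0.739 for 60S proteins, 0.226 for 2-cell-like genes and 0.15 for p53 targets, well above the preset 0.01. For such lists the preset value may have made the calls, and the 2 reasons for a lost call were not separated. Overlap between knockdowns was set against 50 simulated tables with unchanged groups and shared controls.

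The genes named follow a rule fixed at the same time: the 4 targeted genes, the 8 largest called changes in each direction whose libraries did not overlap the controls and for which the third library had the same sign, up to 4 members of each list with the smallest adjusted p, and 16 genes always considered. For siRpl11 against the others, 6 were taken each way. Tcstv3 was not tested. Genes named outside that rule are 2-cell-like genes with a single copy and epithelial genes, chosen after values were seen.

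The scripts were tested on simulated data with the real genes, means and spread, in which 200 of 12249 genes were changed in siRpl11. Of 50 genes changed by each fold, 52% were recovered at 1.2-fold, 94% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, with 14 calls among 12049 unchanged genes. The changed genes were drawn from those not low in siNT. Far fewer genes were changed than were called in the data (8685 in siRpl11), which makes the adjusted threshold stricter. The shares recovered thus check the scripts and do not carry over to the data or to genes of low FPKM. A p53 list shifted by 0.5 log2 was called, with 0 of the other lists called.

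Alternatives were a pseudocount of 0.1, no filter, quantile normalization, median-ratio scaling, the replicate number as a block, all 15 libraries with the table as a covariate, only the groups compared, an absolute log2 fold change of at least 1, and leaving out each library in turn. A loess correction for transcript length and GC content, available for 99.2% of the genes tested, was added after the data were seen. Counting and plotting used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.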

Results

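Gene expression was measured by RNA sequencing in E14 mouse embryonic stem cells after knockdown of 1 of 4 proteins of the large ribosomal subunit (Rpl11, Rpl14, Rpl18 or Rpl23) or after a non-targeting siRNA (siNT). Each of the 5 groups had 3 libraries. Replicates 1 and 2 of every group shared 1 table and entered all main tests (10 libraries, n = 2 per group). The third library of each group came from a separately normalized table. It gave the direction and size of differences there, and a covariance between tables. It entered tests only where all 15 libraries are named. Values are FPKM as deposited, and absolute depth is unknown; relative to the first siNT library of the same table, depth ranged from 0.698 to 1.39 and from 1.00 to 1.26. Fold changes are on the log2(FPKM + 1) scale, which understates genes with low FPKM, and are given as estimate ± SE with limma's adjusted p. FPKM values are mean ± SD with n = 2. Counts of list members that passed are over all genes tested, and those adjusted over the list alone were the same unless given. The p-values measure only the spread between these libraries, which may be technical, since the labels do not say that replicates were separate cultures.

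The targeted genes were compared first, which checks the labels. Rpl11 was at 177 ± 13.4 FPKM in siRpl11 and 737 ± 49.7 in siNT, so 24.0% remained (log2 fold change -2.05 ± 0.08, adjusted p = 3.62e-08). Rpl14 was at 617 ± 16.8 in siRpl14 and 1195 ± 28.2 in siNT, with 51.6% remaining (-0.95 ± 0.05, adjusted p = 1.60e-07). Rpl18 was at 642 ± 40 in siRpl18 and 1967 ± 142 in siNT, with 32.6% remaining (-1.61 ± 0.08, adjusted p = 7.72e-08). Rpl23 was at 424 ± 16.5 in siRpl23 and 1168 ± 60.3 in siNT, with 36.3% remaining (-1.46 ± 0.07, adjusted p = 9.68e-08). In the third libraries 19.9%, 38.5%, 31.2% and 31.1% remained, respectively. No target fell when another gene was the target. The genes that were not the target rose in siRpl11 (Rpl14 0.19, Rpl18 0.30 and Rpl23 0.41), calls that quantile normalization ended for Rpl14 (0.08) and Rpl18 (0.06). The Rpl14 call in siRpl11 also ended with all 15 libraries (0.15), and the Rpl18 call ended without siNT replicate 1 (0.22) or siRpl11 replicate 2 (0.25). Rpl23 also rose in siRpl18 (0.20), a call that ended without siNT replicate 1 (0.15), without siRpl18 replicate 2 (0.12), with no filter and with only the groups compared. In siRpl14 Rpl23 missed the threshold (0.17, adjusted p = 0.0582) and passed with quantile normalization (0.29), the replicate block (adjusted p = 0.00045), all 15 libraries (0.20), the length and GC correction (0.19), without siRpl14 replicate 1 (0.23) and without siRpl18 replicate 1 (adjusted p = 0.0368) or 2 (adjusted p = 0.0370). Rpl14 in siRpl23 (0.09, adjusted p = 0.131) passed with quantile normalization (0.23), the replicate block (adjusted p = 0.0164) and the length and GC correction (0.13). Rpl11 in siRpl18 (0.03) and siRpl23 (0.05) passed only with quantile normalization (0.23 and 0.22).

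**Figure D1:**
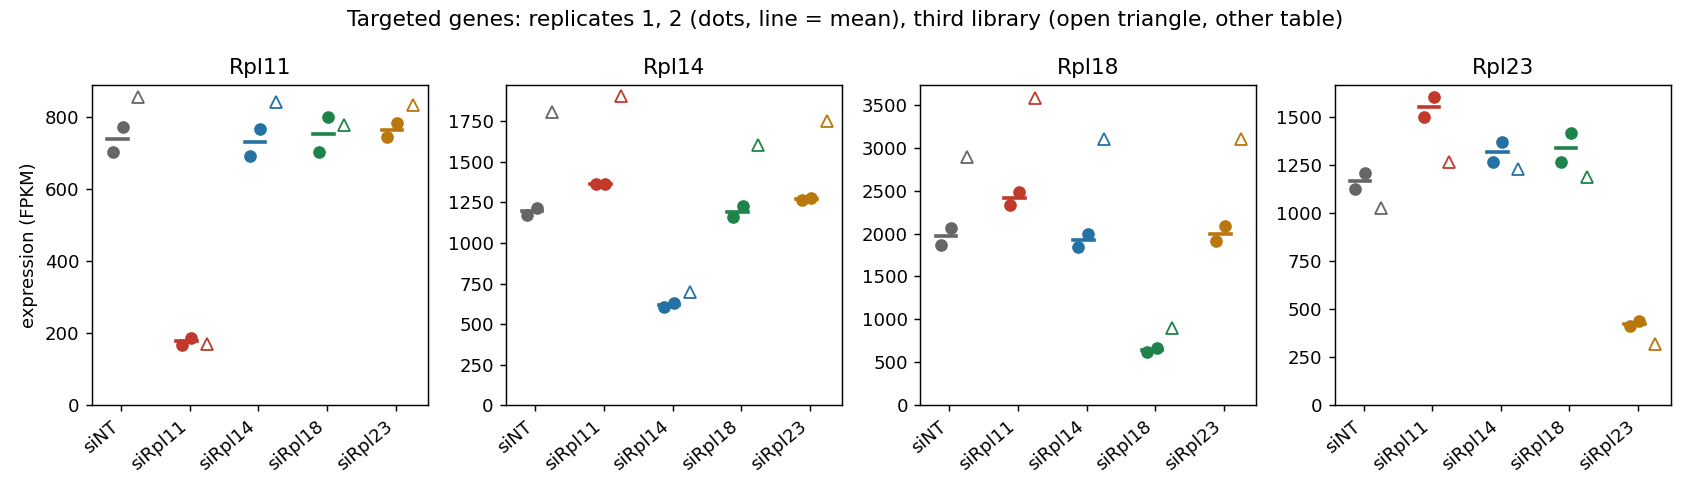
FPKM of each targeted gene (vertical axes, linear from 0) by siRNA group; dots are replicates 1 and 2, the line is their mean and the open triangle is the third library, which was normalized in another table. Each gene is lowest in its own knockdown, from 24.0% of siNT for Rpl11 to 51.6% for Rpl14.

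The first comparison asked what loss of Rpl11 did to the transcriptome. Gadd45g, a stress-inducible growth regulator, went from 1.39 ± 0.101 FPKM in siNT to 24.2 ± 1.37 in siRpl11 (log2 fold change 3.40 ± 0.06, adjusted p = 5.13e-10). Pim2, a survival kinase, went from 10.5 ± 0.265 to 105 ± 0.539 (3.21 ± 0.06, adjusted p = 5.13e-10), and Otx2, a transcription factor of formative pluripotency, from 8.68 ± 0.487 to 78.3 ± 0.394 (3.04 ± 0.05, adjusted p = 3.41e-10). Nupr1, a stress-induced chromatin factor, fell from 57.1 ± 0.710 to 8.66 ± 0.745 (-2.59 ± 0.13, adjusted p = 1.30e-07). Vegfa, which encodes an angiogenic growth factor, fell from 28.4 ± 1.90 to 4.46 ± 0.293, and Phgdh, the first enzyme of serine synthesis, from 138 ± 8.86 to 31.1 ± 1.26. Of 12249 genes tested, 3342 rose and 5343 fell, with 241 and 650 of them changed by 2-fold or more; the median of all genes was -0.11. Among called genes 38.5% rose, against 50.9% after quantile normalization (4269 rose and 4119 fell), which moved the median of all genes by 0.12, and 47.4% after median-ratio scaling.

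Among 42 p53 targets, 28 rose and 6 fell in siRpl11, with a median of 0.46 (camera adjusted p = 3.43e-08, and adjusted p = 0.194 with an estimated correlation). Mdm2, the ubiquitin ligase of p53, went from 41.6 ± 0.511 to 143 ± 5.48 FPKM (1.76 ± 0.04), Plk2, a stress kinase, rose by 2.58 ± 0.04 and Ccng1, a cyclin, by 0.54 ± 0.04. Cdkn1a, which encodes the cell-cycle inhibitor p21, was at 50.4 ± 2.99 and 53.9 ± 2.57 (0.09 ± 0.06, adjusted p = 0.192); it passed with median-ratio scaling (0.19), the length and GC correction (0.19) and all 15 libraries (0.21). Trp53 itself rose from 186 ± 5.07 to 542 ± 3.8 FPKM. The formative list rose, with 13 of 16 members higher and 1 lower, a median of 0.77 (adjusted p = 2.88e-06, and adjusted p = 0.194 with an estimated correlation), and with Sall2 at 2.96 and Lef1 at 2.24. ATF4 targets fell, with 25 of 27 lower and 2 higher and a median of -1.01 (adjusted p = 8.01e-06, and adjusted p = 0.194 with an estimated correlation); Asns, which makes asparagine, fell by 1.78. The unfolded protein response list fell, with 12 of 16 lower and 2 higher. The median was -0.48 (adjusted p = 0.0280, and adjusted p = 0.360 with an estimated correlation). Ribosome biogenesis genes rose, with 32 of 39 higher and 2 lower. The median was 0.34 (adjusted p = 7.75e-10, and adjusted p = 0.194 with an estimated correlation).

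The untargeted 60S proteins had a median of 0.17 in siRpl11, with 18 of 45 higher and 2 lower (camera adjusted p = 0.000930, and adjusted p = 0.673 with an estimated correlation). Quantile normalization ended this call (0.02, adjusted p = 0.679), whereas median-ratio scaling kept it (0.27, adjusted p = 0.000419). The 40S proteins had a median of 0.28, with 22 of 32 higher (23 adjusted over the list alone) and 2 lower, and kept the call under quantile normalization (0.15; adjusted p = 1.64e-05 before it, and adjusted p = 0.53 with an estimated correlation). Rpl3, a core 60S protein, fell from 1379 ± 48.8 to 726 ± 29.2 FPKM. Translation factors and TOP genes had a median of 0.13, with 8 of 20 higher and 4 lower (adjusted p = 0.0434, and adjusted p = 0.440 with an estimated correlation). That call ended with quantile normalization (0.05), the length and GC correction (0.08), without siNT replicate 1 (0.13, adjusted p = 0.0565) and without siRpl11 replicate 2 (0.10). Median-ratio scaling kept the TOP call (0.23, camera adjusted p = 0.0194). Ribosomal protein genes have many processed pseudogenes, so their values are uncertain where reads could be split.

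Members of the 2-cell-like list, expressed in the embryo at the 2-cell stage and in rare embryonic stem cells, did not pass as a list in siRpl11 (median -0.34, adjusted p = 0.129), with 2 of 32 higher and 16 lower; the length and GC correction gave a call (-0.39, adjusted p = 0.0274). Zscan4d, which acts on telomeres in that state, fell from 22.9 ± 1.39 to 11.7 ± 0.820 FPKM, whereas Zfp750, an epidermal transcription factor, rose from 1.89 ± 0.102 to 8.65 ± 0.166. Zscan4, Usp17l and Tdpoz genes are near-identical copies between which reads could be split, so single members are uncertain. Pluripotency genes went both ways in siRpl11 (11 higher and 16 lower of 28, and 11 and 17 adjusted over the list alone; median -0.18, adjusted p = 0.742). Nanog, a core pluripotency factor, fell from 438 ± 10.5 to 192 ± 4.29 FPKM (-1.19 ± 0.04, adjusted p = 1.98e-08). In the trophectoderm list 5 of 16 were higher and 7 lower, with a median of -0.08 but a mean of 0.04 and an upward test (adjusted p = 0.567). G1-S (median -0.22, adjusted p = 0.177) and G2-M genes (median -0.13, adjusted p = 0.562) did not pass as lists, though quantile normalization gave G1-S a call (-0.21, adjusted p = 0.0178).

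**Figure D2:**
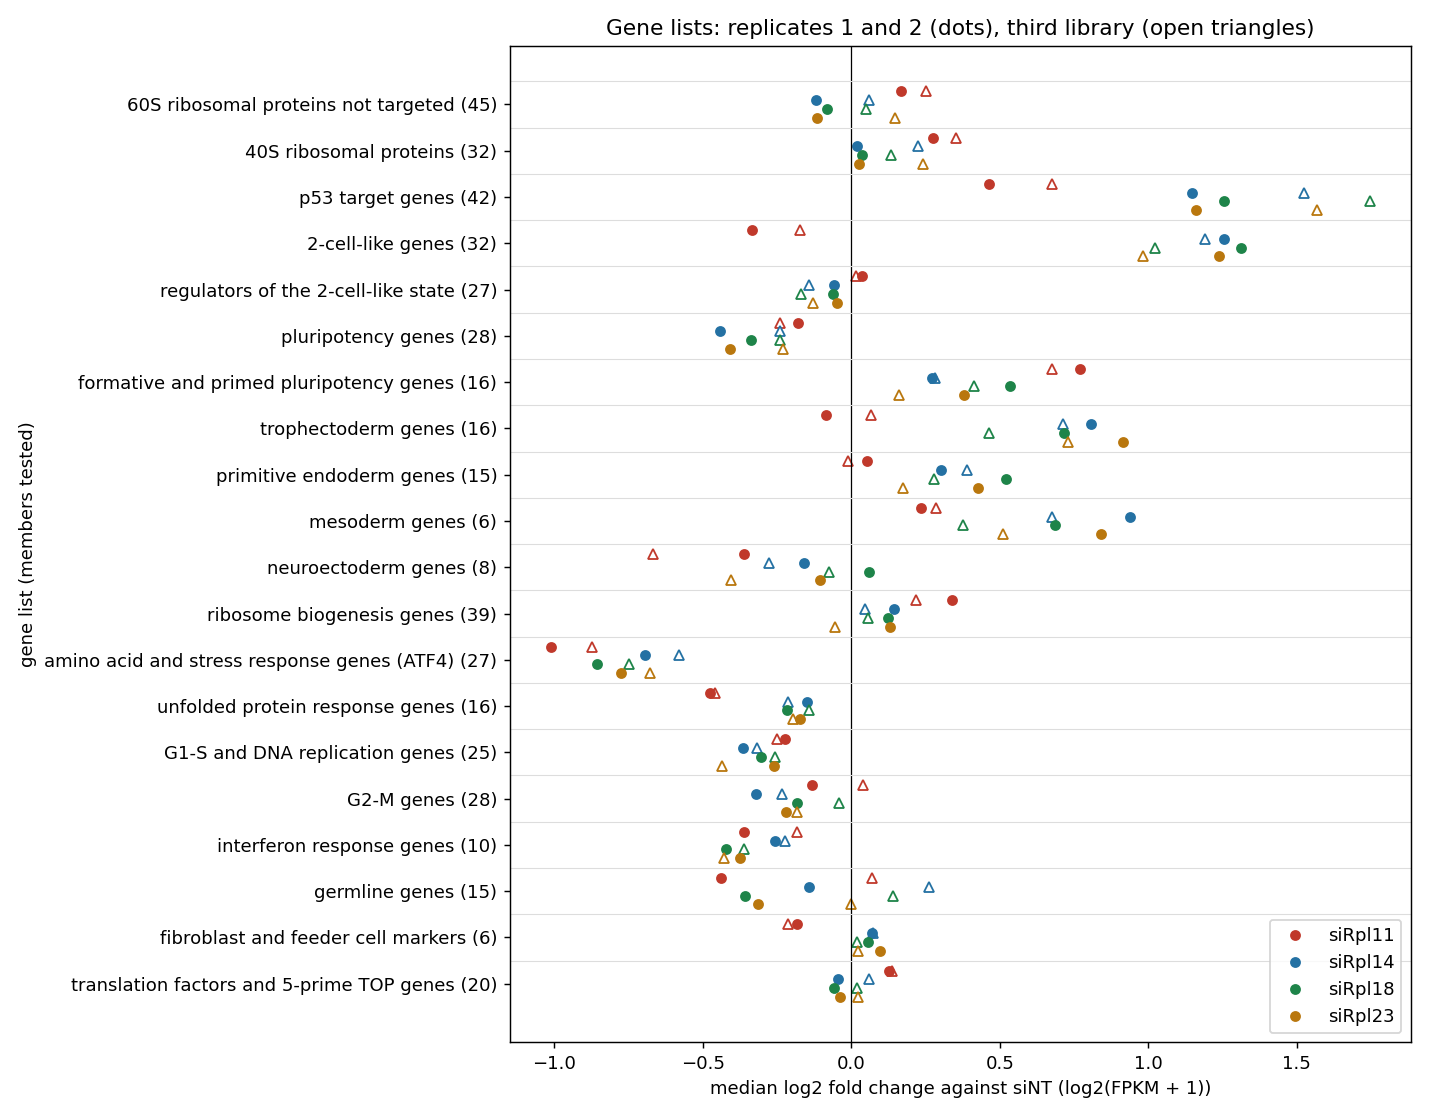
Median log2 fold change against siNT (horizontal axis) of each gene list (vertical axis, with the number of members tested) by knockdown (color); dots are replicates 1 and 2, and open triangles are the third libraries, normalized in another table. The 2-cell-like list stands at -0.34 in siRpl11 and at 1.25, 1.31 and 1.24 in siRpl14, siRpl18 and siRpl23.

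The next comparison asked the same of Rpl14. Fgfbp1, which carries fibroblast growth factors, went from 2.99 ± 1.29 FPKM in siNT to 101 ± 3.20 in siRpl14 (4.71 ± 0.16, adjusted p = 1.06e-08). Perp, a p53-induced membrane protein, went from 9.28 ± 0.354 to 166 ± 4.06 (4.02 ± 0.06, adjusted p = 1.52e-10), and Cyr61, a matricellular protein, from 4.1 ± 0.360 to 66.3 ± 2.71 (3.72 ± 0.06, adjusted p = 1.61e-10). Nupr1 fell to 7.56 ± 1.28 (-2.77 ± 0.13, adjusted p = 8.98e-08) and Chac1, a glutathione-degrading enzyme, fell from 13.1 ± 0.719 to 3.06 ± 0.275. In all, 4074 genes rose and 3618 fell, with 553 and 195 changed by 2-fold or more and a median of all genes of 0.02; quantile normalization turned the balance to 3617 that rose and 4190 that fell (median -0.03). Of 42 p53 targets 38 rose and 3 fell, with a median of 1.15 (camera adjusted p = 2.55e-14, and adjusted p = 0.194 with an estimated correlation). Mdm2 reached 275 ± 2.54 FPKM (2.70 ± 0.04) and Cdkn1a 114 ± 2.08 (1.17 ± 0.06). All 32 tested genes of the 2-cell-like list rose, with a median of 1.25 (adjusted p = 7.41e-13, and adjusted p = 0.194 with an estimated correlation). The list had 48 genes fixed and 42 in the table. Members low in siNT could pass the filter through knockdowns where they were high, so this direction is partly selected. Zscan4d rose to 54.8 ± 1.25 FPKM and Zfp352, a zinc finger gene of the 2-cell stage, from 0.820 ± 0.0392 to 4.13 ± 0.337.

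In siRpl14 cells ATF4 targets fell, with 19 of 27 lower and 4 higher, a median of -0.70 (adjusted p = 1.27e-05, and adjusted p = 0.194 with an estimated correlation), but Ddit4, an inhibitor of mTORC1 and member of that list, rose by 1.53. Trophectoderm genes rose (12 of 16 higher and 2 lower; median 0.81, adjusted p = 0.00110, and adjusted p = 0.194 with an estimated correlation), among them Krt8 at 2.11 and Gata3 at 2.07. G1-S genes fell, with 18 of 25 lower and 1 higher (19 and 1 adjusted over the list alone). The median was -0.36 (adjusted p = 1.03e-05, and adjusted p = 0.194 with an estimated correlation). G2-M genes fell likewise, with 22 of 28 lower and 1 higher (22 and 2 adjusted over the list alone). The median was -0.32 (adjusted p = 8.02e-07, and adjusted p = 0.194 with an estimated correlation). Pluripotency genes fell, with 17 of 28 lower and 8 higher (median -0.44, adjusted p = 0.0152, and adjusted p = 0.194 with an estimated correlation), and Nanog was at 243 ± 7.12 FPKM. Formative genes rose (10 of 16 higher and 1 lower; median 0.27, adjusted p = 0.0174, and adjusted p = 0.194 with an estimated correlation), a call that ended with all 15 libraries (0.22, adjusted p = 0.0851).

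Weaker calls in siRpl14 concerned 3 further lists. Mesoderm genes had 5 of 6 higher and 1 lower (median 0.94, adjusted p = 0.0441, and adjusted p = 0.336 with an estimated correlation), with Wnt3 at 2.52. That call ended without siNT replicate 2 (0.91, adjusted p = 0.0523), without siRpl14 replicate 1 (0.91, adjusted p = 0.0507), with all 15 libraries (0.83), with the replicate block (adjusted p = 0.0571) and with only the groups compared (adjusted p = 0.0503). Ribosome biogenesis genes had 21 of 39 higher and 4 lower. The median was 0.15 (adjusted p = 0.0425, and adjusted p = 0.53 with an estimated correlation). This call ended without siNT replicate 1 (0.13, adjusted p = 0.0789), without siRpl14 replicate 2 (0.11), with median-ratio scaling (0.12) and with all 15 libraries (0.10). The 60S list had 16 of 45 lower and 3 higher (10 and 2 adjusted over the list alone; median -0.12, adjusted p = 0.0363, and adjusted p = 0.811 with an estimated correlation), a call that ended with quantile normalization (-0.05), with all 15 libraries (-0.04), without siNT replicate 2 (-0.07) and without siRpl14 replicate 1 (-0.07, adjusted p = 0.211). The 40S list was not called (median 0.02, adjusted p = 0.787) except after quantile normalization (0.09, adjusted p = 0.0142).

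Knockdown of Rpl18 was compared with siNT next. Perp rose to 243 ± 23.6 FPKM (4.56 ± 0.06, adjusted p = 4.22e-11), Nkx2-9, a ventral neural transcription factor, rose from 1.23 ± 0.558 to 38.7 ± 1.88 (4.17 ± 0.13, adjusted p = 4.84e-09), and Neurod1, a neuronal transcription factor, from 2.22 ± 0.242 to 43.7 ± 3.66 (3.8 ± 0.08, adjusted p = 3.18e-10). Stra8, a gene of meiotic entry, fell from 21.4 ± 0.398 to 4.39 ± 0.407 (-2.06 ± 0.09, adjusted p = 4.93e-08), and Phgdh fell by 2.05. In total 4022 genes rose and 4253 fell, with 637 and 307 changed by 2-fold or more and a median of all genes of -0.02. Of the p53 targets 38 rose and 3 fell, with a median of 1.25 (camera adjusted p = 4.46e-15, and adjusted p = 0.194 with an estimated correlation); Mdm2 was at 373 ± 3.37 FPKM (3.13 ± 0.04) and Cdkn1a at 129 ± 4.38. All 32 tested genes of the 2-cell-like list, of 48 fixed and 42 in the table, rose (median 1.31, adjusted p = 3.05e-13, and adjusted p = 0.194 with an estimated correlation), with Zscan4d at 48.4 ± 4.81 and Zfp352 at 5.91 ± 0.154. Again the filter could admit members through knockdowns where they were high.

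In siRpl18 cells 19 of 27 ATF4 targets fell and 6 rose. The median was -0.85 (adjusted p = 0.000378, and adjusted p = 0.260 with an estimated correlation). G1-S genes fell in 22 of 25 cases and rose in 2. The median was -0.30 (adjusted p = 6.84e-05, and adjusted p = 0.198 with an estimated correlation). Of the G2-M genes 16 of 28 fell and 3 rose (median -0.18, adjusted p = 0.0133, and adjusted p = 0.426 with an estimated correlation), a call that ended with all 15 libraries (-0.15). Formative genes rose, with 11 of 16 higher and 2 lower (11 and 3 adjusted over the list alone; median 0.53, adjusted p = 0.00631, and adjusted p = 0.194 with an estimated correlation), and trophectoderm genes too, with 11 of 16 higher and 2 lower. The median was 0.72 (adjusted p = 0.0114, and adjusted p = 0.194 with an estimated correlation). Primitive endoderm genes rose (10 of 15 higher and 2 lower; median 0.52, adjusted p = 0.0336, and adjusted p = 0.194 with an estimated correlation), with Fst at 1.67. Pluripotency genes fell, with 18 of 28 lower and 8 higher. The median was -0.34 (adjusted p = 0.0434, and adjusted p = 0.194 with an estimated correlation). That call ended with quantile normalization (-0.36), with only the groups compared (adjusted p = 0.0503), without siNT replicate 2 (-0.33, adjusted p = 0.0536) and without siRpl18 replicate 2 (-0.34, adjusted p = 0.0513). Ribosome biogenesis genes missed the threshold (median 0.12, adjusted p = 0.0553) and passed without siNT replicate 2 (0.15), without siRpl18 replicate 1 (0.13), with no filter (0.12), with median-ratio scaling (0.14) and with the length and GC correction (0.13). The 60S list was not called (median -0.08, adjusted p = 0.202) except without siNT replicate 1 (-0.13) or siRpl18 replicate 2 (adjusted p = 0.0365), and the 40S list (0.04) only after quantile normalization (0.10).

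Rpl23 knockdown was the last compared with siNT. Fgfbp1 rose to 88.7 ± 2.43 FPKM (4.53 ± 0.16, adjusted p = 1.11e-08), Perp to 191 ± 7.13 (4.22 ± 0.06, adjusted p = 6.84e-11) and Cyr61 to 71.0 ± 1.60 (3.82 ± 0.06, adjusted p = 9.45e-11). Nupr1 fell to 7.21 ± 1.34 (-2.83 ± 0.13, adjusted p = 6.44e-08) and Pycr1, an enzyme of proline synthesis, from 20.9 ± 1.08 to 4.09 ± 0.1. Together 4277 genes rose and 3776 fell, with 620 and 251 changed by 2-fold or more and a median of all genes of 0.02; quantile normalization turned this balance to 3795 that rose and 4356 that fell (median -0.03). Of the p53 targets 36 rose and 3 fell (37 and 3 adjusted over the list alone), with a median of 1.16 (camera adjusted p = 4.71e-14, and adjusted p = 0.194 with an estimated correlation); Mdm2 was at 350 ± 16.8 FPKM (3.04 ± 0.04) and Cdkn1a at 115 ± 8.53. In the 2-cell-like list 31 of 32 tested members rose and 0 fell (median 1.24, adjusted p = 7.68e-12, and adjusted p = 0.194 with an estimated correlation), with Zscan4d at 52.2 ± 4.96 and Zfp352 at 4.21 ± 0.883. Here too the filter could admit members through knockdowns where they were high.

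ATF4 targets fell in siRpl23, with 19 of 27 lower and 4 higher (20 and 5 adjusted over the list alone). The median was -0.78 (adjusted p = 1.84e-05, and adjusted p = 0.194 with an estimated correlation). Trophectoderm genes rose, with 12 of 16 higher and 2 lower (median 0.91, adjusted p = 0.00145, and adjusted p = 0.194 with an estimated correlation), among them Hand1 at 2.04. G1-S genes fell in 19 of 25 cases and rose in 1 (20 and 1 adjusted over the list alone). The median was -0.26 (adjusted p = 5.46e-05, and adjusted p = 0.194 with an estimated correlation). Of 28 G2-M genes 21 fell and 2 rose. The median was -0.22 (adjusted p = 6.49e-05, and adjusted p = 0.260 with an estimated correlation). Pluripotency genes fell (18 of 28 lower and 8 higher; median -0.41, adjusted p = 0.0160, and adjusted p = 0.194 with an estimated correlation), and formative genes rose (11 of 16 higher and 2 lower, 11 and 3 adjusted over the list alone). The median was 0.38 (adjusted p = 0.0160, and adjusted p = 0.194 with an estimated correlation). Ribosome biogenesis genes rose, with 22 of 39 higher and 2 lower (21 and 2 adjusted over the list alone; median 0.13, adjusted p = 0.0172, and adjusted p = 0.464 with an estimated correlation), but not with all 15 libraries (0.07, adjusted p = 0.15). The 60S list was not called (median -0.11, adjusted p = 0.0980) except without siNT replicate 1 (-0.13), without siRpl23 replicate 2 (-0.12) and with the replicate number as a block (adjusted p = 0.0206), and the 40S list (0.03) only after quantile normalization (0.12).

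**Figure D3:**
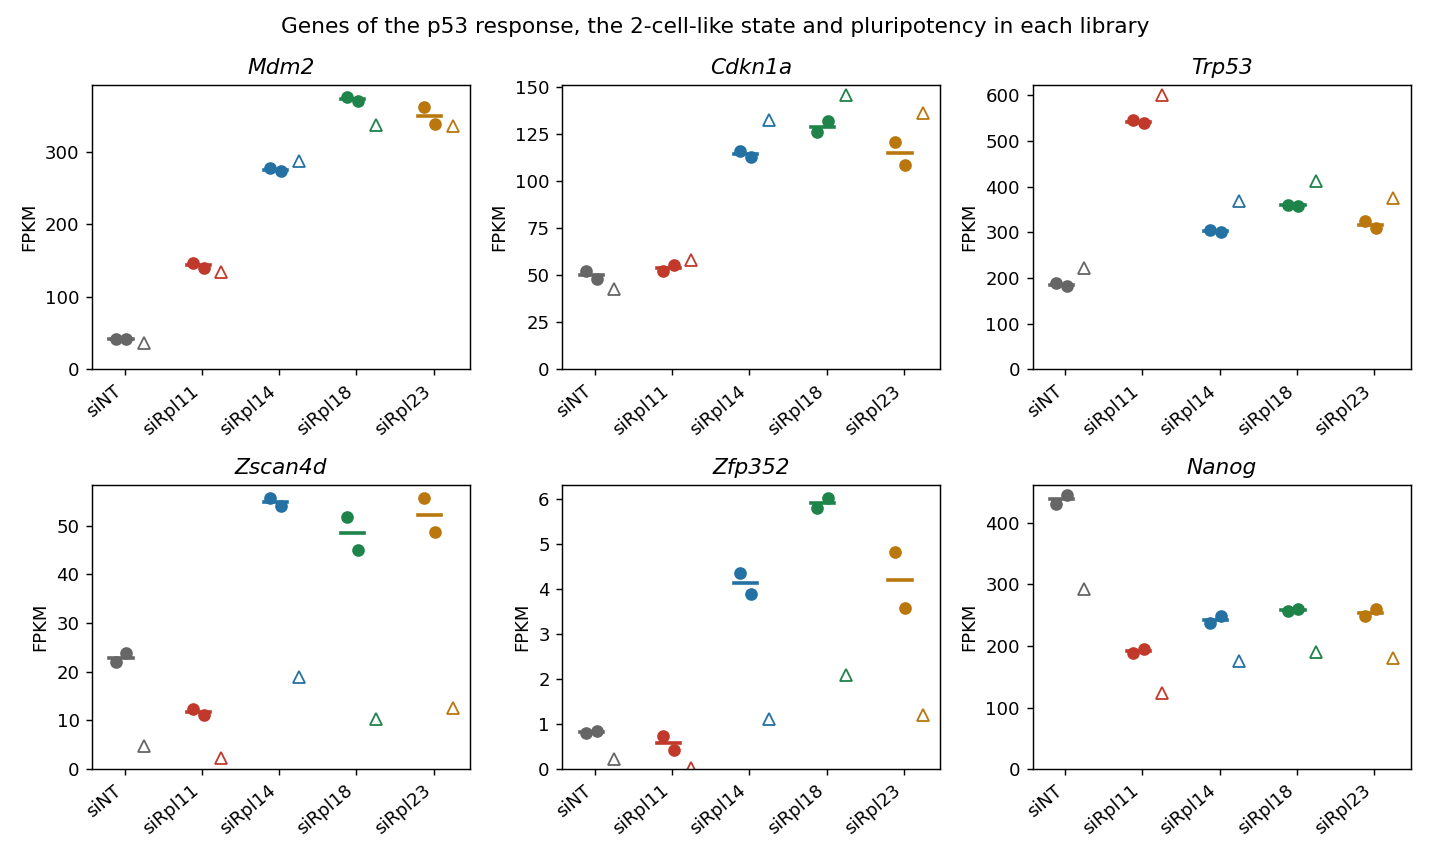
FPKM (vertical axes) by siRNA group for single genes; dots are replicates 1 and 2, the line is their mean and the open triangle is the third library, which was normalized in another table. Mdm2 rose in every knockdown, from 41.6 in siNT to 143 in siRpl11 and 373 in siRpl18, whereas Zscan4d was at 22.9 in siNT, 11.7 in siRpl11 and 54.8 in siRpl14.

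Genes fixed in advance were also followed over the 4 knockdowns in the order siRpl11, siRpl14, siRpl18 and siRpl23. Pou5f1, the core pluripotency factor Oct4, was at 0.18, -0.31, -0.31 and -0.30. Its siRpl11 call ended without siNT replicate 1 (0.14, adjusted p = 0.117) or siRpl11 replicate 2 (0.14, adjusted p = 0.128), and its other 3 calls ended with quantile normalization (-0.04, -0.02 and -0.05). Sox2, a partner of Oct4, rose in all 4 (0.31, 0.12, 0.35 and 0.20), but its siRpl14 call ended without siNT replicate 2 (0.11, adjusted p = 0.0893), without siRpl14 replicate 1 (0.10, adjusted p = 0.126), with all 15 libraries (0.09) and with only the groups compared (adjusted p = 0.0624). Klf4, a naive pluripotency factor, fell in all 4 (-0.99, -0.75, -0.26 and -0.60), but its siRpl18 call ended with all 15 libraries (-0.05), and in the third libraries it differed by 0.38 in siRpl18 and by -0.00 in siRpl23. Nanog fell in all 4 (-1.19, -0.85, -0.76 and -0.79). Dux, which activates 2-cell-stage genes, was at 0.22 (adjusted p = 0.0504), 0.89, 1.06 and 0.86, and its siRpl11 value passed with a pseudocount of 0.1 (0.56), with no filter, quantile normalization (0.30), median-ratio scaling (0.25), the replicate block and all 15 libraries (0.29). Dux lay near the floor, at 0.337 and 0.393 FPKM in siNT, 0.535 and 0.641 in siRpl11 and 0 in the third siNT library. A rise in siRpl11 is therefore uncertain under any of these settings. Myc did not pass in any of the 4 (-0.17, -0.02, -0.11 and 0.07), except in siRpl11 without siRpl18 replicate 1 (adjusted p = 0.0271) or 2 (adjusted p = 0.0268), with only the groups compared (adjusted p = 0.0255) or with all 15 libraries (-0.29), and in siRpl18 without siRpl18 replicate 1 (-0.25). Rpl22l1, a paralog of Rpl22, passed in none (-0.23, -0.17, -0.31 and -0.21).

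Rpl5, which joins the 5S ribonucleoprotein with Rpl11, did not pass in siRpl11 (0.07, adjusted p = 0.458) and was lower in siRpl14 (-0.28), siRpl18 (-0.26) and siRpl23 (-0.25), 3 calls that quantile normalization ended (-0.06, -0.03 and -0.05). They also depended on single libraries, though none of them ended with the replicate block. Rpl5 was higher in replicate 2 than in replicate 1 in all 5 groups, a difference left unbalanced when a single library is left out. The siRpl14 call ended without siNT replicate 2 (adjusted p = 0.0684) or siRpl14 replicate 1 (-0.18), and the siRpl18 call without siNT replicate 2 (adjusted p = 0.0831) or siRpl18 replicate 1 (-0.16). In siRpl23 the Rpl5 call ended with no filter (adjusted p = 0.0561), without siNT replicate 1 (adjusted p = 0.0525) or 2 (adjusted p = 0.0983) and without siRpl23 replicate 1 (adjusted p = 0.10) or 2 (adjusted p = 0.0542).

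Lists called in none of the 4 comparisons with siNT are given first, in the same order. The primitive endoderm, mesoderm, unfolded protein response and TOP lists follow, only for the knockdowns in which they were not called. Neuroectoderm genes had medians of -0.36, -0.16, 0.06 and -0.11, but means of -0.00, 0.43, 0.41 and 0.44, since Neurod1 rose in each. Interferon response genes had medians of -0.36, -0.26, -0.42 and -0.37, germline genes of -0.44, -0.14, -0.36 and -0.31, and regulators of the 2-cell-like state of 0.03, -0.06, -0.06 and -0.05 (means 0.13, 0.01, -0.03 and 0.01). Fibroblast and feeder markers had medians of -0.18, 0.07, 0.06 and 0.10; Vim, an abundant mesenchymal filament gene, was at 97.2 ± 1.39 FPKM in siNT, 89.2 ± 1.81 in siRpl11, 190 ± 4.74 in siRpl14, 231 ± 14.4 in siRpl18 and 183 ± 0.357 in siRpl23, while Thy1 fell in all 4 (-1.55, -0.87, -0.89 and -0.81). Primitive endoderm medians were 0.05 (mean -0.02), 0.30 and 0.43 in siRpl11, siRpl14 and siRpl23, and the last passed with no filter (0.38). Mesoderm medians were 0.23 (mean -0.07), 0.69 and 0.84 in siRpl11, siRpl18 and siRpl23. The unfolded protein response list had medians of -0.15, -0.22 and -0.17 in siRpl14, siRpl18 and siRpl23, and the last passed with the replicate block (adjusted p = 0.0450) and all 15 libraries (-0.18). Translation factors and TOP genes had medians of -0.04, -0.06 and -0.04 there, but means of 0.00, 0.02 and 0.02.

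A further comparison asked whether siRpl11 differed from the other 3 knockdowns; Rpl11 protein binds Mdm2 when ribosome assembly fails. Pim2 was at 105 ± 0.539 FPKM in siRpl11 and at 27.4 ± 1.11, 22.5 ± 1.47 and 25 ± 1.47 in siRpl14, siRpl18 and siRpl23 (log2 difference 2.04 ± 0.05, adjusted p = 1.88e-09). Sct, the hormone secretin, was at 2.13 ± 0.148 in siRpl11 and at 31.5 ± 2.78, 17.8 ± 2.33 and 27.3 ± 1.43 in the others (-3.04 ± 0.10, adjusted p = 7.18e-09), and Cpz, a carboxypeptidase, differed by -2.68 ± 0.07 (adjusted p = 2.03e-09). In siRpl11 2251 genes were higher and 5419 lower than in the others, with 36 and 489 differing by 2-fold or more. Of those called, 29.3% were higher, against 56.8% after quantile normalization (4267 higher and 3242 lower), which moved the median of all genes from -0.12 by 0.16, and 45.6% after median-ratio scaling (3502 higher and 4173 lower). The F test over the 4 knockdowns called 7453 genes. Between pairs of the others far fewer differed: 63 between siRpl14 and siRpl23, 430 between siRpl18 and siRpl23 and 1747 between siRpl14 and siRpl18, against 6536 to 7248 between siRpl11 and each of them.

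All 32 tested genes of the 2-cell-like list were lower in siRpl11 than in the others, with a median difference of -1.70 (camera adjusted p = 2.99e-13, and adjusted p = 0.194 with an estimated correlation). Zscan4d differed by -2.05 ± 0.07, Zfp352 by -1.85 ± 0.10 and Tmem92 by -1.87 ± 0.06. The list had 48 genes fixed and 42 in the table. The filter could admit members through the other knockdowns, as for Zfp352, at 0.740 and 0.424 FPKM in siRpl11, so this direction is partly selected. Of 42 p53 targets 39 were lower and 0 higher (median -0.69, adjusted p = 4.35e-11, and adjusted p = 0.194 with an estimated correlation), among them Mdm2 (-1.2 ± 0.04), Cdkn1a (-1.13 ± 0.05) and Perp (-2.21 ± 0.05), whereas Trp53 was higher by 0.73 ± 0.03. Formative genes were higher (10 of 16 higher and 4 lower; median 0.42, adjusted p = 0.000153, and adjusted p = 0.194 with an estimated correlation), with Dnmt3b at 1.02 and Zic2 at 1.17. Ribosome biogenesis genes were higher (25 of 39 higher and 2 lower; median 0.19, adjusted p = 7.25e-12, and adjusted p = 0.194 with an estimated correlation), as were G1-S genes (12 of 25 higher and 6 lower, 13 and 6 adjusted over the list alone). The median was 0.10 (adjusted p = 0.000865, and adjusted p = 0.260 with an estimated correlation). G2-M genes were also higher (15 of 28 higher and 3 lower; median 0.14, adjusted p = 4.64e-05, and adjusted p = 0.260 with an estimated correlation), and so were regulators of the 2-cell-like state (13 of 27 higher and 5 lower, 14 and 6 adjusted over the list alone). The median was 0.10 (adjusted p = 0.000612, and adjusted p = 0.324 with an estimated correlation). ATF4 targets did not pass as a list (median -0.15, adjusted p = 0.417), though Ddit4 was lower by 1.21, and neither did interferon response genes (median -0.06 with an upward test, adjusted p = 0.634), germline genes (-0.27) or fibroblast and feeder markers (-0.49, with Vim at -1.16).

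The 60S list was higher in siRpl11 than in the others, with 38 of 45 higher and 0 lower (40 and 0 adjusted over the list alone). The median was 0.24 (camera adjusted p = 1.57e-12, and adjusted p = 0.360 with an estimated correlation). Quantile normalization ended the call (0.03, adjusted p = 0.318), whereas median-ratio scaling kept it (0.35, adjusted p = 1.85e-10). The 40S list was higher too, with 23 of 32 higher and 0 lower. The median was 0.23 (adjusted p = 6.64e-09, and adjusted p = 0.413 with an estimated correlation). Quantile normalization turned the test's direction (0.02, adjusted p = 0.878), whereas median-ratio scaling kept the call (0.34, adjusted p = 1.25e-07). Translation factors and TOP genes had 13 of 20 higher and 2 lower. The median was 0.18 (adjusted p = 5.46e-05, and adjusted p = 0.194 with an estimated correlation). They lost the call under quantile normalization (0.10) but not with median-ratio scaling (0.29, adjusted p = 9.15e-05). Pluripotency genes had 14 of 28 higher and 10 lower. The median was 0.10 (adjusted p = 0.0107, and adjusted p = 0.194 with an estimated correlation). They too lost the call under quantile normalization (0.06) but not with median-ratio scaling (0.21, adjusted p = 0.0214). Quantile normalization makes the highest values of all libraries alike, where ribosomal protein genes lie, so it can remove a shift they share. These calls thus depend on the scaling.

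Lineage lists were lower in siRpl11 than in the others, with calls near the threshold. Trophectoderm genes (10 of 16 lower and 2 higher, 11 and 2 adjusted over the list alone; median -0.72, adjusted p = 0.0434, and adjusted p = 0.282 with an estimated correlation) lost the call without siNT replicate 1 (adjusted p = 0.0533) or 2 (adjusted p = 0.0536), without siRpl23 replicate 1 (-0.73, adjusted p = 0.0573), with the replicate block, with only the groups compared (adjusted p = 0.0527) and with the length and GC correction (-0.64); Krt8 differed by -2.42 ± 0.09. Mesoderm genes (4 of 6 lower and 0 higher; median -1.02, adjusted p = 0.0396, and adjusted p = 0.328 with an estimated correlation) lost it with no filter (-0.15), the replicate block and the length and GC correction (-0.97). Primitive endoderm genes (10 of 15 lower and 0 higher; median -0.36, adjusted p = 0.0295, and adjusted p = 0.194 with an estimated correlation) lost it with quantile normalization (-0.08) and the length and GC correction (-0.32). The unfolded protein response list (12 of 16 lower and 0 higher; median -0.28, adjusted p = 0.0342, and adjusted p = 0.360 with an estimated correlation) lost it without siRpl11 replicate 1 (-0.25, adjusted p = 0.0634) and with median-ratio scaling (-0.17). Neuroectoderm genes were not called (median -0.54, adjusted p = 0.0913) except with quantile normalization (-0.36) and median-ratio scaling (-0.44).

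**Figure D4:**
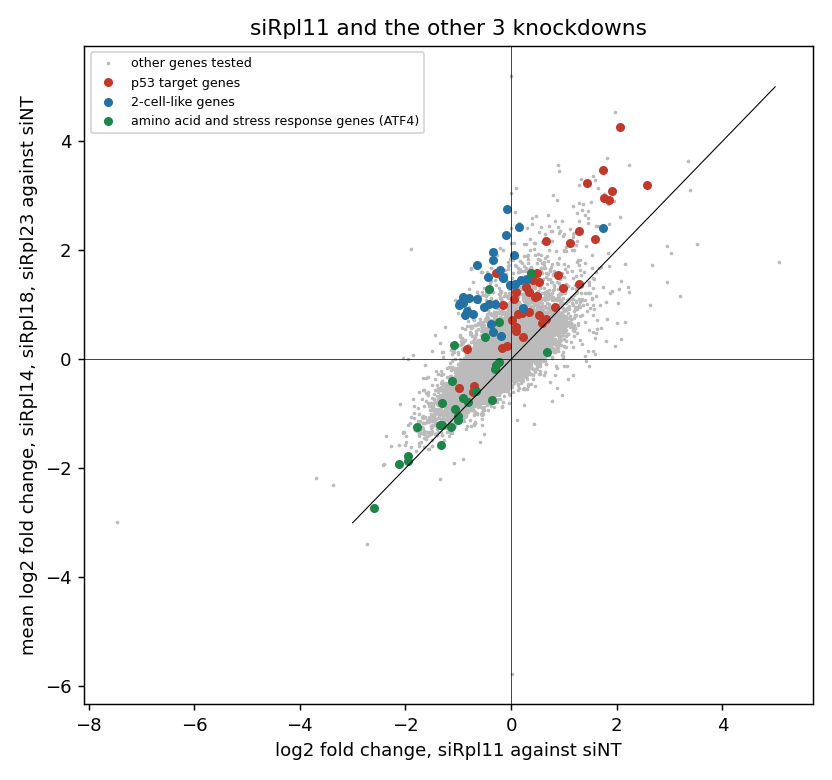
Log2 fold change against siNT of each tested gene in siRpl11 (horizontal axis) and its mean in siRpl14, siRpl18 and siRpl23 (vertical axis), with colored points for the lists named in the key and a line where both are equal. Points of the 2-cell-like list lie above the line (median of siRpl11 minus the others -1.70), and so do those of the p53 targets (median -0.69, highest -0.08).

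The comparisons with siNT were set against each other to ask how far the knockdowns share their changes. Phgdh, Nupr1, Vegfa and Pycr1 fell and Mdm2, Plk2 and Trp53 rose in all 4. In all 4 knockdowns 2104 genes rose and 2781 fell, 4885 together, and 118 rose and 142 fell by 2-fold or more in each. Independent lists of the same sizes would share 127 and 169 genes, and unchanged groups simulated against shared controls (50 simulations) shared 0. With no group changed, hardly any gene passes in a simulated contrast. This 0 therefore cannot show how many of the shared calls come from the shared controls. Of 3366 genes that rose in siRpl14, siRpl18 and siRpl23, 2104 rose and 397 fell in siRpl11, and of 3115 that fell in those 3, 2781 fell and 57 rose in siRpl11. Correlations of fold changes across genes, which are not independent replicates, were 0.678 to 0.707 between siRpl11 and the others and 0.937 to 0.952 among the others. Simulated unchanged groups gave 0.498. That value is set by the shared control group when all differences are noise, so it does not measure how much of the observed correlations comes from shared controls. The mean covariance was 0.264, against 0.0116 simulated. A split of the controls would leave 1 library on each side and was not made, so part of the excess may come from the shared controls. Between tables, which share no library, the mean covariance was 0.226, a value computed after the data were seen.

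The third libraries tested the direction of single genes in a separately normalized table, with no error of their own. Mdm2 differed there by 1.86, 2.95, 3.18 and 3.17 in siRpl11, siRpl14, siRpl18 and siRpl23, and Zscan4d by -0.82, 1.77, 0.95 and 1.23. Zfp352, at 0.820 FPKM in siNT, was at 0.228 in the third siNT library and 0.0282 in the third siRpl11 library. Of the called genes 91.8%, 91.0%, 90.7% and 88.9% had the same sign in the third library, and 96.7% in siRpl11 against the others. Among called genes under 0.25 on the log2 scale the shares were 80.8%, 80.4%, 80.3% and 77.6%. Of the called lists 2 had a median of the opposite sign there: the 60S list in siRpl14 (0.06, with 31 of 45 members higher, a list whose call quantile normalization ended) and ribosome biogenesis genes in siRpl23 (-0.05, with 21 of 39 lower).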

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

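The tests on single-copy members, on the sum of the other 2-cell-like members and on p53 targets below were chosen after the result was seen. The lists here drew attention because limma's camera found siRpl11 to differ from the mean of the other 3 knockdowns at the preset correlation, which none of them passed with an estimated correlation (smallest adjusted p = 0.194). Median log2 differences below 0 were -1.70 for 2-cell-like genes, -1.02 for mesoderm genes, -0.72 for trophectoderm genes, -0.69 for p53 targets, -0.36 for primitive endoderm genes and -0.28 for unfolded protein response genes. Medians above 0 were 0.42 for formative genes, 0.24 for 60S and 0.23 for 40S ribosomal proteins, 0.19 for ribosome biogenesis genes, 0.18 for translation factors and TOP genes, 0.14 for G2-M genes, 0.10 for G1-S genes, 0.10 for pluripotency genes and 0.10 for regulators of the 2-cell-like state. Quantile normalization ended the calls of the 60S, 40S, translation factor, pluripotency and primitive endoderm lists, with the 40S test turned in direction. Median-ratio scaling kept all of these calls.

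The widest gap, in 2-cell-like genes, was set against technical and biological explanations. Scaling of the libraries by the authors is argued against as the whole cause by the size of the median-ratio shifts, -0.096 to 0.045 log2. Shifts so small could not close this gap, so the median difference of -1.61 after that scaling adds no separate support. Reads shared between near-identical copies are argued against by 6 single-copy members (Arg2, Tmem92, Zfp352, Lmx1a, Spz1 and Zfp750), with a median difference of -1.43. The FPKM summed over the other 26 tested members differed by -2.19, in the same direction. Copy number was not checked for these 26, so the sum may also hold single-copy genes. A weaker p53 response in siRpl11 stays open, since p53 targets were lower there as well (median difference -0.69), but both differ between the same groups, and no manipulation of p53 was analysed here. The depth of knockdown also differed, with 24.0% of Rpl11, 51.6% of Rpl14, 32.6% of Rpl18 and 36.3% of Rpl23 remaining. In siRpl14, siRpl18 and siRpl23 the 2-cell-like medians against siNT were close (1.25, 1.31 and 1.24). The highest was in siRpl18, the deepest of these knockdowns. Each depth belongs to a different target gene, so these groups cannot separate depth from the protein lost. The knockdown in siRpl11 was deeper still. That depth and another role of Rpl11 may also contribute and were not tested.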

How the results depend on the processing

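The length and GC correction was chosen after seeing the data, and the other alternatives before. The counts of called genes, of their overlap and of called lists stayed within 1.5 times their values under a pseudocount of 0.1, no filter, quantile normalization, median-ratio scaling, all 15 libraries, only the groups compared, and the length and GC correction. Requiring an absolute log2 fold change of at least 1 left 891 genes in siRpl11, 748 in siRpl14, 944 in siRpl18, 871 in siRpl23, 525 in siRpl11 against the others, 728 in the F test and 260 shared by all 4, as a stricter threshold must give fewer. Among such genes 98.4%, 98.4%, 97.8% and 98.5% had the same sign in the third library in siRpl11, siRpl14, siRpl18 and siRpl23. With an estimated correlation 0 of 100 list tests were called in place of 52. That setting also leaves the test fewer degrees of freedom, so correlation alone need not have ended these calls. Quantile normalization reversed Rpl11 in siRpl14 (0.17), Rpl14 in siRpl18 (0.12), Rps23 in siRpl11 against the others (-0.038) and the test of the 40S list in siRpl11 against the others (median 0.022). Neither Rpl11 in siRpl14 nor Rpl14 in siRpl18 had passed before it, and the cause was not tested. In siRpl11 the share of called genes that rose went from 38.5% to 50.9%, and in siRpl11 against the others from 29.3% to 56.8%. For single named genes in their comparisons, quantile normalization ended 13 calls and added 7, and all 15 libraries ended 5 and added 4. For list tests, quantile normalization ended 9 calls and added 5, all 15 libraries ended 6 and added 1, and the length and GC correction ended 4 and added 2. Over all single libraries left out, 32 calls of named genes and 14 of lists ended, and 7 and 6 were added.

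Leaving out each library in turn gave 7688 to 8687 genes in siRpl11, 6730 to 7713 in siRpl14, 7438 to 8238 in siRpl18, 7045 to 8058 in siRpl23, 6153 to 7677 in siRpl11 against the others, 5853 to 7438 in the F test, 4233 to 4703 in all 4, and 49 to 53 list tests. The lone library of a group was then assumed to vary like the other groups. The labels do not say that a replicate number marks a shared culture or day. Deviations of libraries with the same number correlated by -0.086 to 0.195 over 10 pairs of groups, so not every library went best with its own number, and no pairing was assumed. A part is still shared by number: 20.4% of genes differed with 1 sign between replicates 1 and 2 in all 5 groups, against 6.25% by chance, a test chosen after the data were seen. With the replicate number as a block 9103, 8271, 8776 and 8554 genes were called in siRpl11, siRpl14, siRpl18 and siRpl23, 8227 in siRpl11 against the others, 8333 in the F test and 5279 in all 4, with 51 list tests. The controls were not split, which would leave 1 library on each side. Simulated unchanged groups took that place, which bears on the covariance but not on the correlation or the count of shared calls. Depth of 0.698 to 1.39 relative to the first siNT library limits genes of low FPKM. In the simulation of siRpl11 against siNT 52% of genes changed by 1.2-fold were recovered. That share does not measure this limit, since the changed genes were not low in siNT and far fewer were changed than were called in the data.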

Other observations

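The gene lists of the next paragraphs, and the test of chance values from shared controls, were chosen after values were seen. Of 45 tests on 9 such lists, 22 passed limma's camera at the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.173). Glycolysis enzymes fell in all 4 knockdowns, 14 of 14 in each, with medians of -0.80, -0.53, -0.74 and -0.69 in siRpl11, siRpl14, siRpl18 and siRpl23. Hypoxia-inducible genes fell in 17, 16, 17 and 19 of 23 cases and rose in 2, 3, 3 and 3 (17 fell in siRpl14 adjusted over the list alone; medians -0.69, -0.34, -0.43 and -0.56). Cholesterol synthesis genes fell in 16, 15, 17 and 14 of 18 and rose in 0 (16 fell in siRpl14 adjusted over the list alone; medians -0.49, -0.44, -0.53 and -0.42). YAP-TEAD targets, a list that holds Ptpn14, which had been seen, rose in siRpl14, siRpl18 and siRpl23 (medians 0.68, 0.73 and 0.71), with 8 of 13 higher and 3 lower in each, and did not pass in siRpl11 (0.25, adjusted p = 0.0842).

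Against the other 3 knockdowns, siRpl11 had lower epithelial keratin and junction genes (20 of 22 lower and 0 higher, median -0.70, camera adjusted p = 7.80e-06, and adjusted p = 0.173 with an estimated correlation), a list with Krt19, Sfn, Cldn4 and Cldn6, which had been seen. None of the lists in this paragraph passed with an estimated correlation. Lysosome genes were lower (19 of 21 lower and 0 higher, median -0.35), and snoRNA host genes (10 of 15 higher and 1 lower, median 0.24), oxidative phosphorylation genes (11 of 24 higher and 2 lower, median 0.11) and proteasome subunits (11 of 24 higher and 2 lower, median 0.08) were higher. Against siNT in siRpl11, epithelial (median -0.63) and lysosome genes (-0.53) fell, whereas snoRNA hosts (-0.06), proteasome subunits (-0.03) and oxidative phosphorylation genes (0.01) did not pass. In the other 3 knockdowns these 5 lists did not pass against siNT.

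Most genes tested changed in each knockdown, with a largely shared direction. Chance values of the shared controls are argued against as the main cause: fold changes of different knockdowns taken from different tables, which share no library, kept 85.8% of the covariance within the table. Replicates so close that small chance differences pass the test are argued against too, since 79.7% of called genes under 0.25 on the log2 scale had the same sign in the third library. For length and GC content, the number of 2-fold calls after the correction was 96.4% of that before, but most called genes changed by less than 2-fold. All calls numbered 8577, 7743, 8351 and 8020 of 12156 genes after the correction, in siRpl11, siRpl14, siRpl18 and siRpl23. Before it they numbered 8685, 7692, 8275 and 8053 of 12249. These counts argue against length and GC content as the main cause, as far as the correction removes their trends. A shared response to loss of a 60S protein is a hypothesis that may explain the pattern, but a response to siRNAs with active targets, or culture differences common to the knockdowns, were not tested.

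ATF4 targets were lower in all 4 knockdowns. Scaling by the authors is argued against as the whole cause by the size of the median-ratio shifts, -0.096 to 0.045 log2. Shifts so small could not account for these medians, so the highest of the 4 medians after that scaling (-0.72) adds no separate support. Fewer cells or a fresher medium in the knockdown cultures may contribute: hypoxia-inducible genes, chosen without those already seen, were also lower, with the highest of the 4 medians at -0.34. Cell number and the timing of medium changes are not given in the sources used here, so this stays open beside a direct effect of the knockdowns.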
